A study of Mus musculus with 10 samples.

How the data were processed

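RNA was extracted from snap-frozen, pulverised mouse skin with silica columns, per the labels' protocols, and libraries were made by polyA selection with the Illumina TruSeq mRNA v2 kit, which does not mark strand. They were sequenced as 50-cycle single-end reads on an Illumina HiSeq instrument, per the labels' protocols. The labels gave genotype and sex for each of 10 mice, 5 Klk6+ and 5 WT, with 3 males and 2 females in each genotype. Replicate numbers were assigned within each genotype and carry no pairing between genotypes. No batch, litter, body site or hour of collection was given in the sources used here, and age was given as a range for the series. Skin was sampled whole, so a change in a transcript's level can come from the cells that make it or from their share of the tissue.

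The authors deposited 1 table per mouse with a gene symbol, a read count and an FPKM value (fragments scaled to transcript length and to library size). The read counts are whole numbers per gene as deposited by the authors, with different totals per library and no normalization. The FPKM values were scaled by the authors; the scaling total is not given in the sources used here. TopHat2, SAMtools, HTSeq and Cufflinks (2.2.1) and the mouse builds GRCm38 and mm10 are named in the submitters' processing notes, which do not say which tool made which value. The annotation version, the treatment of reads that match several genes, and the strand setting are not given in the sources used here. Values of near-identical gene copies (the Sprr2, Prl2c, stefin, Lce3, Serpinb3 and Krt6 families) and of genes whose exons overlap another gene are therefore uncertain for single members. Gene positions were taken from GENCODE M21 on GRCm38, where 19881 of the 20611 symbols matched as written, 610 matched through a synonym and 120 did not match. Genes encoded by the mitochondrial genome were not analysed here.

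Read counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on genotype (minimum count 10), which left 14861 genes, and libraries were scaled by trimmed mean of M values. Negative binomial quasi-likelihood F tests were run on genotype with sex as a covariate. The genotype effect within each sex and the genotype-by-sex interaction were taken from a model with 4 genotype-by-sex means that shared 1 estimate of the spread (biological coefficient of variation 0.244 in the model with sex as covariate). Adjusted p is the Benjamini-Hochberg value over all genes tested, genes with adjusted p below 0.05 were called, and log2 fold changes are given ± their model standard error. CPM are counts scaled to the library size after these factors, given as mean ± SD over 5 mice. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio of summed counts is given with its exact 95% counting interval. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Shares of counts were compared by two-sided exact permutation tests over the 252 assignments of the 10 libraries to 2 groups of 5.

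Before the data were examined, 33 gene lists were composed from general knowledge of skin, covering epidermal programmes, cytokine axes, stress responses and the other cell types that a skin sample can hold, with 412 tested genes, 10 of them on more than 1 list. Of these lists, 31 had at least 3 tested members and were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; the same test was repeated with an estimated correlation. The antimicrobial, IL-23 and IL-17, and psoriasis lists were the 3 that held with an estimated correlation, out of 22 called with the preset one. The psoriasis list shares S100a8, S100a9 and Lcn2 with the antimicrobial list. Counts of members are given over all genes tested and adjusted over the list alone. The genes named were also set by rule at that stage: Klk6 with 4 receptor genes and 1 inhibitor gene; the 12 genes of largest log2 fold change in each direction among called genes with a mean of at least 1 CPM and no overlap between genotypes; up to 5 members of each list, by smallest p and, where a list did not change, by highest mean level; up to 5 genes per direction of smallest p for the interaction and each sex; and for sex the Y-linked genes and up to 4 others per direction. Genes outside this rule are named where a count of 5 or fewer called for it, and are marked as chosen after their values were seen. A few genes that the rule or such a count would name are not reported here.

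The edgeR, DESeq2 and limma-voom tests of genotype, of genotype within each sex, of the interaction and of sex, limma-trend for genotype, and the list tests were tested on simulated data drawn from the real means and library sizes, with 200 genes, or 5 lists, changed by known folds. The exact permutation tests and the fit with a surrogate variable were not. For the genotype test on 14790 genes, edgeR recovered 14.7% of genes changed 1.5-fold, 63.6% of those changed 2-fold and 92.2% of those changed 4-fold, with 4 false calls. For 2-fold changes it recovered 47.0% in males, 15.2% in females, 6.06% for the interaction and 71.2% for sex. DESeq2 made 49 false calls in the genotype simulation, 48 in males, 45 in females, 45 for the interaction and 34 for sex, against at most 8 by edgeR or limma-voom in any of these. Of 4-fold interactions edgeR recovered 55.4%, DESeq2 75.4% and limma-voom 49.2%. The simulated means were pooled over the genotypes and only 200 genes were changed, while the real genotype test called 10813. A Benjamini-Hochberg cutoff loosens as more genes change. The recovery rates for genotype, over all mice or within a sex, therefore do not describe the real genotype tests. All 5 changed lists of 31 were recovered with 0 false calls by camera and by fry. The simulated genes were independent of each other, so the simulation does not cover the correlation between real genes. When the real libraries were regrouped, splits other than genotype called a median of 18 lists by camera. Those splits still held part of the genotype difference.

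Alternatives fixed at the same stage were other scalings (DESeq2 size factors in edgeR, upper quartile), other filters (none, or at least 1 CPM in 5 libraries), DESeq2 1.42.0, limma-voom (limma 3.58.1), genotype alone, 1 surrogate variable (sva 3.50.0), libraries of 1 sex alone, fry, and leaving out each library in turn. Added after the data were seen were limma-trend on log2(FPKM + 1) of the deposited FPKM and no scaling beyond library size. The others added then were leaving out the muscle list and the 50 most abundant WT genes, and leaving out Klk6+ 3 and Klk6+ 5 together. The muscle and abundant genes were removed from library sizes, scaling and tests alike, which left 14816 genes tested. Adjusted p-values that DESeq2 gave as missing (35 genes) were left missing.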

Results

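Gene expression was measured by mRNA sequencing in the skin of transgenic mice that overexpress kallikrein-related peptidase 6 and of control mice. The protein is a secreted trypsin-like serine protease, encoded by Klk6. In the transgenic animals (Klk6+) a tagged mouse Klk6 transgene was switched on in keratinocytes by a tetracycline transactivator under a bovine keratin 5 promoter, which is active in the absence of doxycycline. Controls (WT) were littermates without both transgenes; per the labels' protocols these could carry 1 of the transgenes without expressing it. Each genotype was represented by 5 mice, 3 males (replicates 1 to 3) and 2 females (replicates 4 and 5), with 1 library per mouse. Total counts ranged from 32798416 to 41970272 in WT and from 26521019 to 39796511 in Klk6+, so that 1 count was worth 0.0230 to 0.0373 CPM, the count scaled to library size. Of 20611 genes listed, 14861 had enough counts to be tested.

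The libraries separated by genotype. The first principal component held 78.3% of the variance and placed all WT libraries at or below -71.9 and all Klk6+ libraries at or above 72.8. The second component (7.85%) set Klk6+ 3 and Klk6+ 5 (-33.4 and -52.1) apart from the other Klk6+ libraries, which lay between 4.32 and 42.2. Spearman correlations across genes were 0.956 to 0.991 within a genotype and 0.780 to 0.879 between genotypes. A check for a library deposited more than once found none (lowest chi-square per degree of freedom within a genotype 40.5, where a repeat would give about 1).

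The targeted gene, Klk6 (chromosome 7, 43824499 to 43832030, plus strand, GRCm38), rose from 18.2 ± 5.17 CPM in WT to 12600 ± 1944 CPM in Klk6+ (mean ± SD, n = 5 each), a log2 fold change of 9.45 ± 0.22 (SE; adjusted p = 5.57e-09). It made up 0.00184% ± 0.000492 of all counts in WT and 1.23% ± 0.151 in Klk6+ (n = 5 each; two-sided exact permutation p = 0.00794, the smallest that 5 against 5 libraries allow). Counts per gene symbol do not tell transgene transcripts from those of the endogenous gene. Per the labels' protocols doxycycline chow was given again at 10 to 11 weeks of age and tissue was collected at 14 to 16 weeks. Doxycycline switches this transgene off, yet Klk6 stood at 10290 to 14770 CPM in all Klk6+ libraries. The order in the protocol and this level are hard to reconcile, and whether the sequenced skins were taken before or after doxycycline was returned is left open here. Among the genes of protease-activated receptors, for which KLK6 is a candidate activator, F2rl2 fell by 1.64 ± 0.36 and F2rl3 fell by 1.80 ± 0.34 on the log2 scale (adjusted p = 0.00201 and 0.000822). Both were low, F2rl2 at 0.698 to 2.21 CPM in WT and 0.340 to 0.737 CPM in Klk6+, with overlap between genotypes. F2rl3 stood at 0.643 to 1.316 CPM in WT and 0.124 to 0.421 CPM in Klk6+. For F2r, which encodes protease-activated receptor PAR1, the log2 fold change was 0.38 ± 0.19 (adjusted p = 0.0971), and for F2rl1 it was 0.11 ± 0.23 (adjusted p = 0.667). Without WT 2, F2r passed the threshold (0.49, adjusted p = 0.0208). Spink5, whose product inhibits epidermal kallikreins, rose by 0.71 ± 0.29 (adjusted p = 0.0483). The Spink5 call was lost with other scalings and without any one of 8 of the 10 libraries, with adjusted p up to 0.155 without Klk6+ 5.

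The main question of the series was which genes differ between Klk6+ and WT skin. The genotypes differed in 10813 of the 14861 genes tested (72.8%), 5603 higher and 5210 lower in Klk6+ with sex as a covariate. Of these, 2340 were at least 2-fold higher and 3048 at least 2-fold lower, and 203 were at least 16-fold higher and 96 at least 16-fold lower. The values of the genotypes did not overlap for 8478 genes (57.0%), where chance gives 0.79%. Transcripts of the 16 skeletal-muscle genes on the list fixed for that tissue took 7.63% ± 1.27 of the counts in WT and 0.744% ± 0.213 in Klk6+ (n = 5 each; two-sided exact permutation p = 0.00794).

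Among the steepest rises besides Klk6, Il22, which encodes the T-cell cytokine interleukin 22, had 0 counts in WT and 686 in Klk6+, at least 264-fold higher against a floor of 3 counts over the group. Prl2c1, of the prolactin family, had 0 and 550 counts, at least 212-fold higher. Il17a, which encodes interleukin 17A, had 1 count in WT and 886 in Klk6+, a ratio of 1020 (95% counting interval 183 to 40500), and Prl2c2 had 2 and 2186 counts, a ratio of 1260 (349 to 10400). The WT counts of both genes all came from WT 3. Klk6+ 3 held 1010 of the Klk6+ counts of Prl2c2, and the fitted log2 fold change was 9.10 without it in place of 9.81. With WT 3 left out no WT counts of either gene remained, and the fitted values were 11.84 for Prl2c2 and 10.49 for Il17a. The main value for Il17a was 9.23. The log2 fold changes of Prl2c5, Gm5416 (a stefin-like gene), Sprr2e, Sprr2f, Sprr2i, Ankk1 and Uox lay between 9.09 ± 0.25 (Uox, urate oxidase) and 9.82 ± 0.86 (Prl2c5). Prl2c5 rose by 9.20 without Klk6+ 4, and Ankk1 by 9.82 without WT 1 in place of 9.10. The Prl2c and Sprr2 families hold near-identical copies among which counting could split reads, so single members are uncertain.

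**Figure D1:**
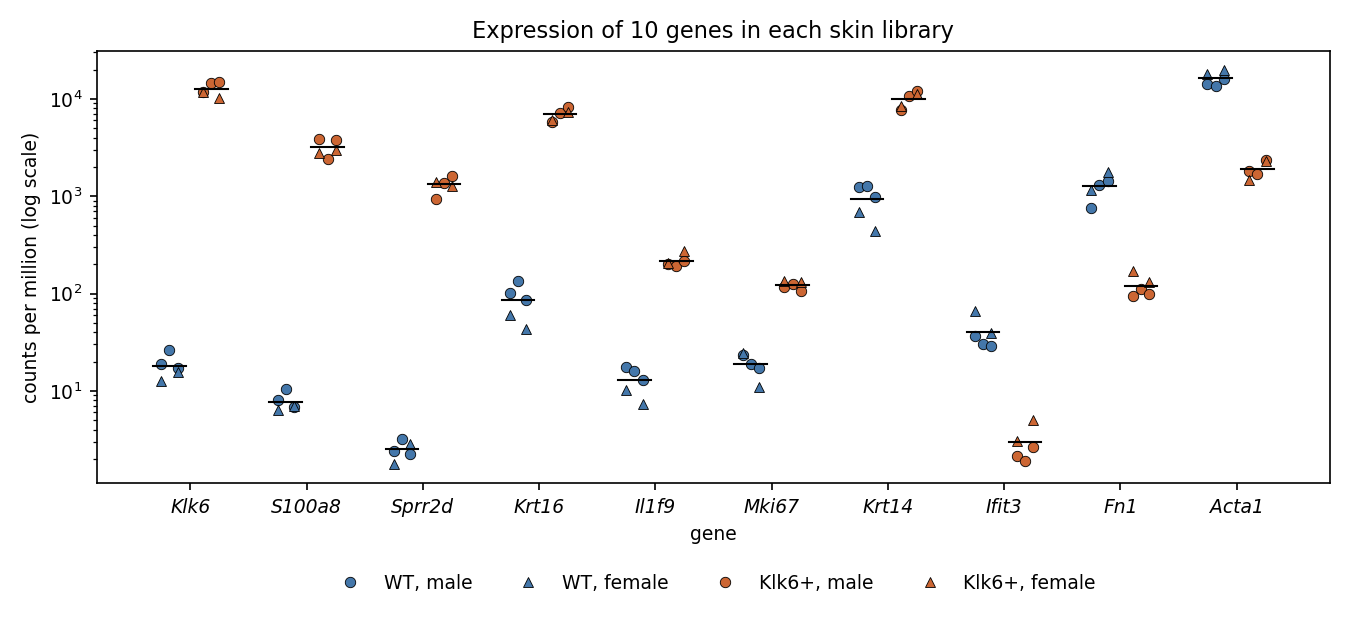
CPM on a log axis of 10 genes in each of the 10 skin libraries; circles are males, triangles females, blue WT and orange Klk6+, and bars are the means of 5 libraries. The genotypes did not overlap for any of these genes, with Klk6 at a mean of 18.2 CPM in WT and 12600 CPM in Klk6+ and the muscle gene Acta1 at 16250 and 1927 CPM.

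Among the steepest falls, Mrgprb3, of a family of sensory and mast-cell receptors, had 1715 counts in WT and 3 in Klk6+, a WT to Klk6+ ratio of 495 (95% counting interval 169 to 2400). The ratios were 264 (90 to 1280) for Odf3l2 and 360 (64.3 to 14300) for Igsf1, whose single Klk6+ count came from Klk6+ 3. F830045P16Rik (-7.66), Dupd1 (-6.87), Upk3b (-6.54), Hamp2 (-6.40), Tgm7 (-6.35), Actc1 (-6.22) and Plcd4 (-6.03, which shares exon sequence with Zfp142) also fell. So did Retnla, which encodes resistin-like molecule alpha, from 1282 ± 1312 to 10.5 ± 2.44 CPM (-6.36 ± 0.53). Mstn, which encodes the muscle growth inhibitor myostatin, fell from 350.4 ± 134 to 4.65 ± 3.03 CPM (-6.28 ± 0.52; n = 5 each throughout). Dupd1 and Actc1 are muscle genes that stood highest in WT 3, and Actc1 fell by 5.34 without WT 3. Other fitted values also moved with 1 library, to -7.11 for Odf3l2 without WT 3, -7.51 for Dupd1 and -7.06 for Hamp2 without Klk6+ 1, and -7.39 for Upk3b without Klk6+ 5.

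Genes of stress keratins and small proline-rich proteins, of kallikreins and of the cell cycle rose in Klk6+. Values from whole skin do not show which cells made the cell-cycle transcripts. All 14 tested genes of stress keratins and small proline-rich proteins, which are low in resting interfollicular epidermis, were higher in Klk6+ (14 adjusted over the list alone), with a median log2 fold change of 8.82, for example Sprr2d (9.04 ± 0.25) and Krt16 (6.43 ± 0.28, from 85.2 ± 35.9 to 6936 ± 970 CPM). Their summed share of counts rose from 0.0969% ± 0.0291 to 3.13% ± 0.653 (n = 5 each; two-sided exact permutation p = 0.00794). The camera test against the other genes gave adjusted p = 2.03e-21, and adjusted p = 0.079 with an estimated correlation. All 9 tested kallikreins other than Klk6 rose (9 adjusted over the list alone; median 3.09), including Klk13 (7.82 ± 0.24), Klk9 (5.31 ± 0.30), Klk8 (3.09 ± 0.17) and Klk7 (2.76 ± 0.22), the last a protease of corneocyte shedding; camera gave adjusted p = 5e-09, and adjusted p = 0.20 with an estimated correlation. All 19 cell-cycle genes rose (19 adjusted over the list alone; median 2.70), for example Mki67 (2.70 ± 0.21) and Top2a (2.70 ± 0.22), with adjusted p = 1.01e-09 and, in contrast, adjusted p = 0.23 with an estimated correlation.

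Genes of late epidermal differentiation moved both ways. Of 17 tested members 11 rose and 5 fell (11 and 5 adjusted over the list alone), with a median of 1.33. Rises included Rptn (5.67 ± 0.39), Casp14 (3.82 ± 0.23), Tgm1 (3.36 ± 0.26) and Krt1 (2.78 ± 0.28), which act in the cornified envelope or the suprabasal filament network. The 5 that fell, named after their values were seen, were the suprabasal keratins Krt77 (-5.87 ± 0.85), Krt2 (-4.08 ± 0.55) and Krt10 (-0.54 ± 0.19) and the barrier protein genes Flg2 (-4.36 ± 0.63) and Lor (-1.01 ± 0.40). Without Klk6+ 5, in which Krt77 and Flg2 were highest among the Klk6+ libraries, these genes fell further (Krt77 -7.04, Flg2 -5.30, Lor -1.60). The calls of Krt10 and Lor were lost without any one of several single libraries, with adjusted p up to 0.0784 without WT 4 for Krt10 and 0.101 without Klk6+ 3 for Lor. The list was called up by camera (adjusted p = 0.0366), with adjusted p = 0.65 with an estimated correlation, and not called without WT 3 (0.0539), without Klk6+ 5 (0.0851) or with genotype alone (0.0666). Its share of counts was 1.25% ± 0.472 in WT and 1.64% ± 0.374 in Klk6+ (n = 5 each, two-sided exact permutation p = 0.19). Of 12 genes of epidermal barrier lipids 11 rose (11 adjusted over the list alone; median 1.90), including Elovl4 (3.21 ± 0.30), which extends very long-chain fatty acids, and Pnpla1 (2.45 ± 0.22), needed for acylceramides (camera adjusted p = 7.52e-05, and adjusted p = 0.26 with an estimated correlation). Sebaceous-gland genes rose in the same libraries (9 of 10, median 2.55).

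Basal keratinocyte genes also split. Krt14 (3.52 ± 0.27) and its partner Krt5 (1.10 ± 0.23) rose, as did Itga6 (0.60 ± 0.23), named after its value was seen. Krt15 (-3.11 ± 0.32), Dst (-2.03 ± 0.20) and Col17a1 (-1.33 ± 0.29) fell; Dst and Col17a1 encode parts of hemidesmosomes, which anchor basal cells. In all 4 rose and 3 fell of 10 (4 and 3 adjusted over the list alone), with a median of 0.20, a mean of -0.02 and a camera direction of down (adjusted p = 0.982). The median was -0.03 without Klk6+ 5. Itga6 was not called without any one of 7 single libraries (adjusted p up to 0.118, without Klk6+ 5) or with other scalings.

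Antimicrobial and alarmin genes rose in all 14 cases tested (14 adjusted over the list alone; median 7.15). The calprotectin subunit genes S100a8 and S100a9 went from 7.74 ± 1.68 to 3170 ± 635 CPM and from 11.1 ± 3.02 to 4736 ± 970 CPM (8.68 ± 0.23 and 8.76 ± 0.24), the siderophore-binding Lcn2 rose by 7.93 ± 0.33 and the beta-defensin Defb3 by 9.02 ± 0.30. Camera gave adjusted p = 2.29e-16, and adjusted p = 0.048 with an estimated correlation. All 12 neutrophil genes tested rose in the same libraries (median 5.96), and S100a8, S100a9 and Lcn2 are transcribed in neutrophils as well as in keratinocytes. Of 27 tested genes that are raised in human psoriasis plaques, a list composed from general knowledge and not from these mice, 21 rose and 3 fell (21 and 3 adjusted over the list alone; median 4.11; camera adjusted p = 2.29e-16, and adjusted p = 0.044 with an estimated correlation). The members S100a8, S100a9, Lcn2, Krt16, Krt6a, Sprr1b, Il1f9, Tgm1 and Cxcl1 are also on other lists given here, so these results are not independent. Serpinb3a (8.64 ± 0.23) and Gjb6 (6.69 ± 0.27), which encodes connexin 30, were among the psoriasis genes that rose. The 3 that moved against the list's name, named after their values were seen, were the interferon-induced Epsti1 (-3.01 ± 0.27), Kynu (-0.94 ± 0.30), of tryptophan breakdown, and Gda (-0.63 ± 0.26), which encodes guanine deaminase. Gda was not called without any one of 7 single libraries, with adjusted p up to 0.149 without WT 3. Serpinb3a belongs to a family of near copies.

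Cytokine genes of the IL-23 and IL-17 axis rose in 13 of 16 cases and fell in 1 (13 and 1 adjusted over the list alone). The median was 4.84, also with Il22 placed at its lower bound, and camera gave adjusted p = 5.74e-07, and adjusted p = 0.036 with an estimated correlation. Il17f (8.63 ± 0.49), the keratinocyte cytokine Il19 (8.61 ± 0.34) and Nfkbiz (3.62 ± 0.18), a mediator of interleukin 17 signalling, rose. The median was 4.23 without WT 1 and 4.12 without WT 4, and Il17f rose by 9.26 without WT 3. In the IL-1 and IL-36 family 9 of 14 rose and 2 fell (9 and 2 adjusted over the list alone; median 2.53; camera adjusted p = 2.04e-06, and adjusted p = 0.23 with an estimated correlation). The genes of the 3 agonist forms of interleukin 36 rose, Il1f6 by 7.72 ± 0.22, Il1f8 by 4.97 ± 0.29 and Il1f9 by 4.11 ± 0.23, and so did that of the receptor antagonist, Il1f5 (2.85 ± 0.19). The decoy receptor gene Il1r2 (-0.89 ± 0.33) and Il1f10 (-1.38 ± 0.49) fell, were named after their values were seen, and lost their calls without any one of several single libraries (adjusted p up to 0.0925 for Il1r2 and 0.07 for Il1f10, both without Klk6+ 1).

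Of 22 chemokine genes 9 rose and 7 fell (9 and 7 adjusted over the list alone), with a median of 0.13 that became -0.15 without Klk6+ 5 and camera adjusted p = 0.354. The neutrophil attractants Cxcl2 (7.74 ± 0.54) and Cxcl1 (6.39 ± 0.47) and Ccl20 (4.89 ± 0.36), which attracts CCR6-bearing lymphocytes, rose, and the eosinophil attractant Ccl24 fell (-4.53 ± 0.33). In the type 2 cytokine axis 5 of 8 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.92; camera adjusted p = 0.293). Il13ra2 (2.64 ± 0.27), a decoy receptor for interleukin 13, Osmr (1.10 ± 0.11), Il4ra (1.09 ± 0.24), Il13ra1 (0.74 ± 0.12) and Il4 (2.36 ± 0.79, named after its value was seen) rose, while Il31ra, the receptor gene of the itch cytokine interleukin 31, fell (-2.87 ± 0.57, and -3.49 without Klk6+ 5). Il4 lost its call without WT 1 (adjusted p = 0.0551) or WT 3 (0.0581).

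Interferon-stimulated genes fell without exception among the 21 tested (21 adjusted over the list alone), with a median of -2.83. Ifit3 went from 40.4 ± 15.3 to 2.96 ± 1.24 CPM (-3.78 ± 0.20) and Ifit1 from 19.7 ± 5.30 to 1.68 ± 0.941 CPM (-3.68 ± 0.28). Usp18, a brake on interferon signalling that interferon itself induces, fell by 3.68 ± 0.16. Camera gave adjusted p = 5.78e-10, and adjusted p = 0.20 with an estimated correlation. In the same libraries the list medians were -2.02 for macrophages and monocytes, -1.82 for dendritic and Langerhans cells and -3.24 for skeletal muscle.

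Markers of immune cells did not move as 1 group. All 12 tested neutrophil genes rose (12 adjusted over the list alone; median 5.96; camera adjusted p = 1.32e-07, and adjusted p = 0.23 with an estimated correlation), including the granulocyte receptor Cxcr2 (4.27 ± 0.30) and the stefin genes BC100530 (8.68 ± 0.21) and Stfa2 (8.21 ± 0.24), which stand in a cluster of near copies. Values from whole skin do not show which cells made the stefin transcripts, so their rise need not reflect neutrophils. The neutrophil median was 5.03 without Klk6+ 3. Of 9 mast-cell genes 8 rose (9 adjusted over the list alone; median 0.94), with Fcer1a (4.35 ± 0.49) and the histamine-forming Hdc (3.17 ± 0.44) ahead; camera gave adjusted p = 0.0384, and adjusted p = 0.48 with an estimated correlation, and the call was lost without WT 2 (0.0505), Klk6+ 1 (0.0557) or Klk6+ 4 (0.0527). Of 15 macrophage and monocyte genes 13 fell (14 adjusted over the list alone; median -2.02), including Adgre1 (-2.66 ± 0.27), Ccr2 (-2.49 ± 0.28) and Csf1r (-2.47 ± 0.30, which shares exon sequence with Hmgxb3); camera gave adjusted p = 0.00117, and adjusted p = 0.46 with an estimated correlation. The one that rose, named after its value was seen, was the endotoxin co-receptor gene Cd14 (1.73 ± 0.51, and 1.05 without Klk6+ 3). Of 13 dendritic and Langerhans cell genes 12 fell (12 adjusted over the list alone; median -1.82), with the class II antigen presentation genes Cd74 (-3.65 ± 0.33) and H2-Aa (-3.61 ± 0.34) and with Cd209a (-2.29 ± 0.23); camera gave adjusted p = 0.000191, and adjusted p = 0.26 with an estimated correlation.

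T-cell genes split, with 4 of 14 up and 7 down (4 and 7 adjusted over the list alone; median -0.50; camera adjusted p = 0.976). The CD3 chains Cd3e (-1.93 ± 0.28) and Cd3g (-1.48 ± 0.23) fell while the activation and regulatory genes Cd5 (3.13 ± 0.31), Icos (2.95 ± 0.22), Ctla4 (1.88 ± 0.24) and Foxp3 (0.83 ± 0.26, named after its value was seen) rose. Only 4 B-cell and plasma-cell genes could be tested; Tnfrsf17 (-3.91 ± 0.64) and Cd79b (-2.42 ± 0.34) fell and 1 rose, with 2 and 1 adjusted over the list alone and camera adjusted p = 0.407. Tnfrsf17 fell by 4.53 without Klk6+ 1.

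Genes of tissues beneath the epidermis fell in Klk6+. All 16 skeletal-muscle genes fell (16 adjusted over the list alone; median -3.24), for example Acta1 (-3.06 ± 0.18), Ckm (-3.78 ± 0.28) and Pvalb (-5.20 ± 0.40); camera gave adjusted p = 4.23e-11, and adjusted p = 0.20 with an estimated correlation. Of 16 genes of dermal collagens and fibroblasts 15 fell (15 adjusted over the list alone; median -1.39), among them Fn1 (-3.43 ± 0.21), which encodes fibronectin, and Dcn (-1.61 ± 0.15), which encodes decorin; the list's share of counts was 3.40% ± 1.71 in WT and 0.947% ± 0.259 in Klk6+ (n = 5 each; two-sided exact permutation p = 0.00794). For this list camera gave adjusted p = 0.00109, and adjusted p = 0.27 with an estimated correlation. All 10 blood endothelial genes fell (10 adjusted over the list alone; median -0.81), including Tek (-1.75 ± 0.22) and Cdh5 (-1.04 ± 0.13), with adjusted p = 0.017 and, differently, adjusted p = 0.46 with an estimated correlation. All 8 Schwann-cell genes fell (8 adjusted over the list alone; median -1.93), including the myelin gene Pmp22 (-1.93 ± 0.18), with adjusted p = 0.00213 and adjusted p = 0.39 with an estimated correlation. Of 12 adipocyte genes 10 fell (11 adjusted over the list alone; median -1.41), including Lep (-3.40 ± 0.46) and Adipoq (-1.58 ± 0.22), and Pparg, the regulator of fat-cell formation, rose (0.95 ± 0.25) and was named after its value was seen; camera gave adjusted p = 0.00213, and adjusted p = 0.26 with an estimated correlation.

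Genes of skin appendages were higher or spread widely. Of 10 sebaceous-gland genes 9 rose (9 adjusted over the list alone; median 2.55), with Elovl3 (5.55 ± 0.54, which shares exon sequence with Pitx3) and the wax-ester synthase gene Awat1 (3.77 ± 0.39); camera gave adjusted p = 0.00698, and adjusted p = 0.46 with an estimated correlation. Of 22 hair-follicle and hair-shaft genes 7 rose and none fell (1 adjusted over the list alone, Foxn1, 2.25 ± 0.28), with a median of 2.50 and camera adjusted p = 0.343. The inner root sheath genes Krt71 (3.02 ± 1.65, adjusted p = 0.123) and Tchh (2.61 ± 1.39, adjusted p = 0.114) were not called; both were called without WT 5 (4.40, adjusted p = 0.0437, and 3.73, adjusted p = 0.0298). The mean level of the hair list was 4.08 to 6.58 log2 CPM in Klk6+ 1, 2 and 4 and near 0 in Klk6+ 3 (-0.02) and Klk6+ 5 (-0.05), against -0.07 to 2.99 in WT. Of 8 melanocyte genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 2.75; camera adjusted p = 0.329). Their mean level was also split within Klk6+, at 4.003 to 4.434 log2 CPM in Klk6+ 1, 2 and 4, 2.661 in Klk6+ 3 and 1.728 in Klk6+ 5, against 0.664 to 2.048 in WT. Tyrp1, of pigment synthesis, rose by 3.28 ± 0.54 (2.66 without Klk6+ 4), and Mitf, the melanocyte transcription factor gene, fell by 1.34 ± 0.15.

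In all, camera called 22 of the 31 lists tested, 12 up and 10 down, and 3 with an estimated correlation. Of 100 splits of the same libraries, the real one included, 8 gave at least 22 called lists. The splits other than genotype called a median of 18, but their groups still differed in the share of each genotype. With fry, which tests each list without setting it against other genes, 26 lists were called, and at most 1 in any other split. With 72.8% of all genes called by genotype, such a test can call many lists whatever their content. In the other splits the genotype difference went into the spread within groups, which holds their counts down. The fry counts therefore do not single out these lists. The 4 that fry added to those of camera were the type 2 cytokine axis (adjusted p = 5.2e-05), chemokines (0.0263) and immediate-early and heat-shock genes (0.0187), called up, and B and plasma cells (0.00165), called down.

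**Figure D2:**
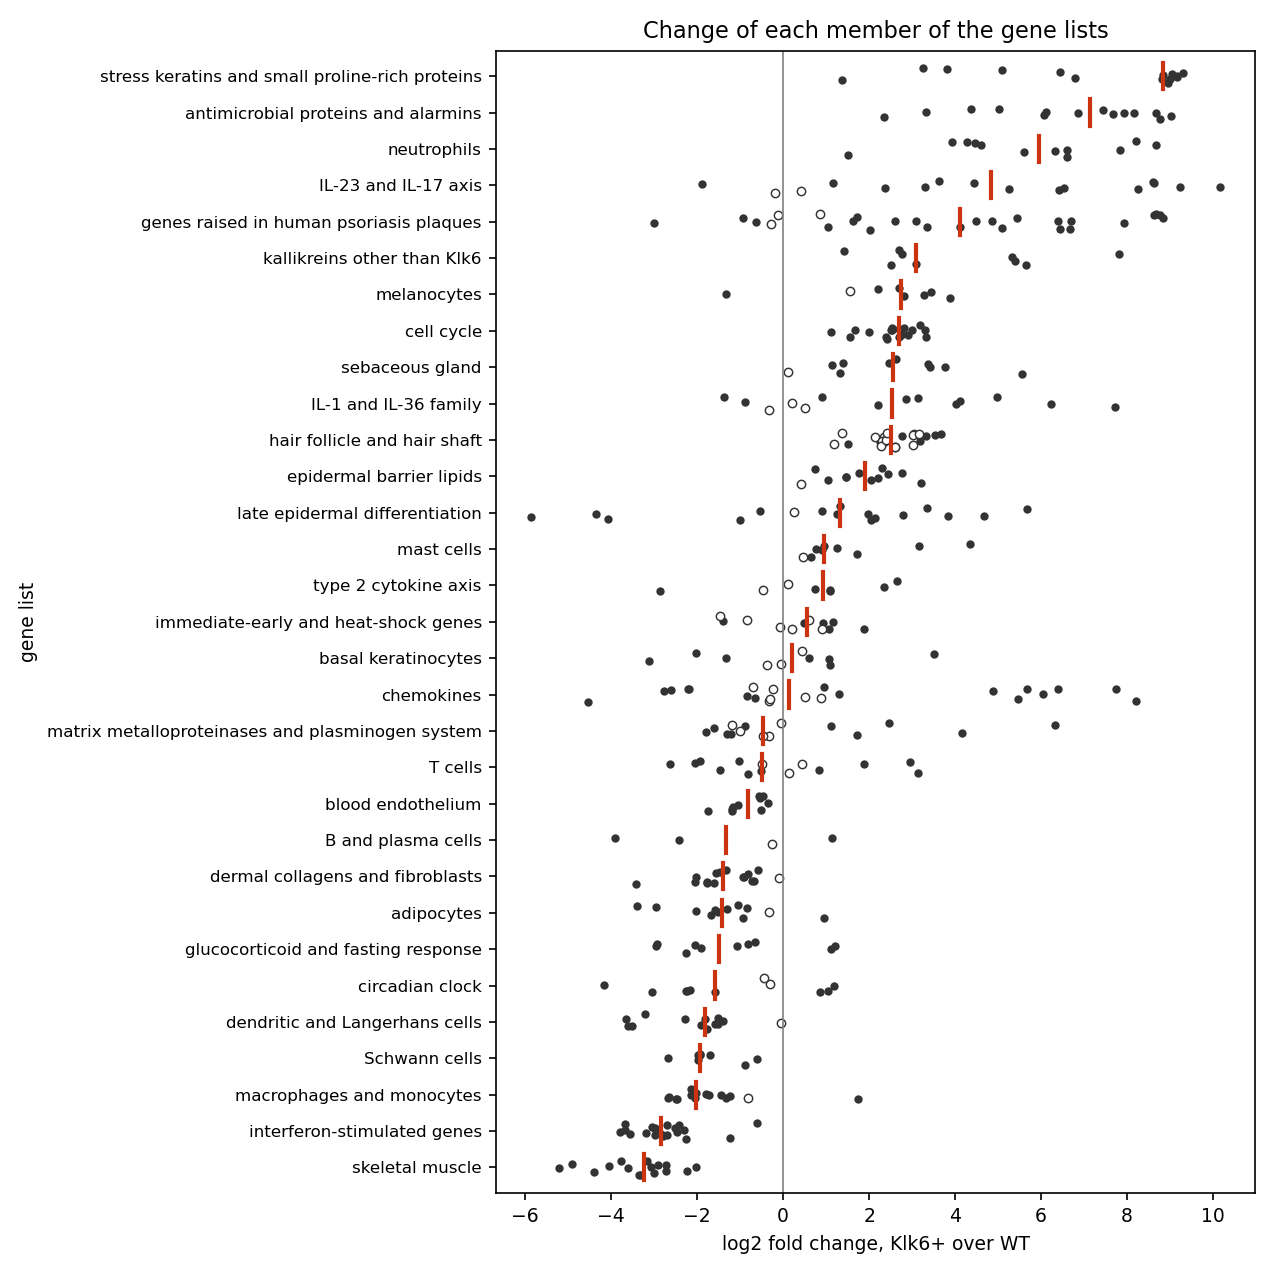
Log2 fold change of Klk6+ over WT for each tested member of the 31 gene lists that had at least 3 tested members; filled points passed adjusted p below 0.05, open points did not, and red bars are list medians. Medians run from -3.24 for skeletal muscle to 8.82 for stress keratins and small proline-rich proteins.

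Among matrix proteases and the plasminogen system 5 of 15 rose and 5 fell (5 and 5 adjusted over the list alone). Mmp8 (6.31 ± 0.91), a neutrophil collagenase, Mmp13 (4.17 ± 0.65), Plaur (2.47 ± 0.48), Timp1 (1.71 ± 0.54) and Mmp11 (1.12 ± 0.42) rose, the last 3 named after their values were seen. Mmp3 (-1.80 ± 0.53), Plat (-1.60 ± 0.23), Serpine2 (-1.29 ± 0.18), Mmp2 (-1.20 ± 0.16) and Plau (-0.88 ± 0.24) fell. The median was -0.47, the mean 0.40 and the camera direction down (adjusted p = 0.624). Mmp11 was not called without any one of 6 single libraries or with genotype alone (adjusted p up to 0.109, without WT 3). Other values moved with 1 library, Mmp8 to 7.49 without WT 2 and 5.55 without Klk6+ 3, Timp1 to 2.49 without WT 2, and Mmp3 to -2.44 without Klk6+ 5.

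Clock genes moved in opposite directions. Of 11 members 6 fell and 3 rose (6 and 3 adjusted over the list alone; median -1.59). Dbp (-4.16 ± 0.29, from 92.0 ± 27.8 to 5.18 ± 1.30 CPM), Nr1d1 (-3.06 ± 0.30), Nr1d2 (-2.25 ± 0.13) and Tef (-2.25 ± 0.23) fell, and Arntl (1.18 ± 0.29), Cry1 (1.05 ± 0.25) and Clock (0.86 ± 0.12) rose; Arntl and Cry1 were named after their values were seen. Dbp and Nr1d1 share exon sequence with Sphk2 and Thra. Camera called the list down (adjusted p = 0.0384), with adjusted p = 0.21 with an estimated correlation, and not without Klk6+ 2 (0.0506), Klk6+ 3 (0.0543), Klk6+ 4 (0.0553) or Klk6+ 5 (0.0637). Glucocorticoid-responsive and fasting-responsive genes fell in 8 of 10 cases and rose in 2 (8 and 2 adjusted over the list alone; median -1.49; camera adjusted p = 0.0384, and adjusted p = 0.40 with an estimated correlation). Txnip (-2.92 ± 0.23), Klf9 (-2.06 ± 0.21) and Tsc22d3 (-1.91 ± 0.19), which glucocorticoids induce, fell. The 2 that rose were Cdkn1a (1.12 ± 0.17), which encodes the cell-cycle inhibitor p21, and the glucocorticoid target Fkbp5 (1.20 ± 0.29, named after its value was seen). The list was not called without WT 2 (0.0674), Klk6+ 1 (0.0557) or Klk6+ 3 (0.0578).

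Immediate-early and heat-shock genes, which can mark handling of tissue, rose in 5 of 12 cases and fell in 1 (5 and 1 adjusted over the list alone; median 0.54; camera adjusted p = 0.365). Junb (1.88 ± 0.33, which shares exon sequence with Prdx2), Hspa1b (1.15 ± 0.14), Ier2 (1.08 ± 0.26), Hspa1a (0.92 ± 0.14) and Jun (0.49 ± 0.15) rose, and Atf3 fell (-1.41 ± 0.51, named after its value was seen, and -2.00 without Klk6+ 2). Atf3 was not called without any one of 5 other single libraries (adjusted p up to 0.059, without Klk6+ 5) or with genotype alone (0.109), and Jun was not called with genotype alone (0.0693). For Egr1 the log2 fold change was 0.20 ± 0.41 (adjusted p = 0.676); without WT 1 it was 0.69 (adjusted p = 0.0333). Only 2 red-cell genes could be tested, Alas2 (0.59 ± 0.98, adjusted p = 0.595, which shares exon sequence with Apex2) and Hba-a2 (-0.08 ± 1.05, adjusted p = 0.951); without WT 3 the value for Alas2 was 1.98 (adjusted p = 0.0365).

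**Figure D3:**
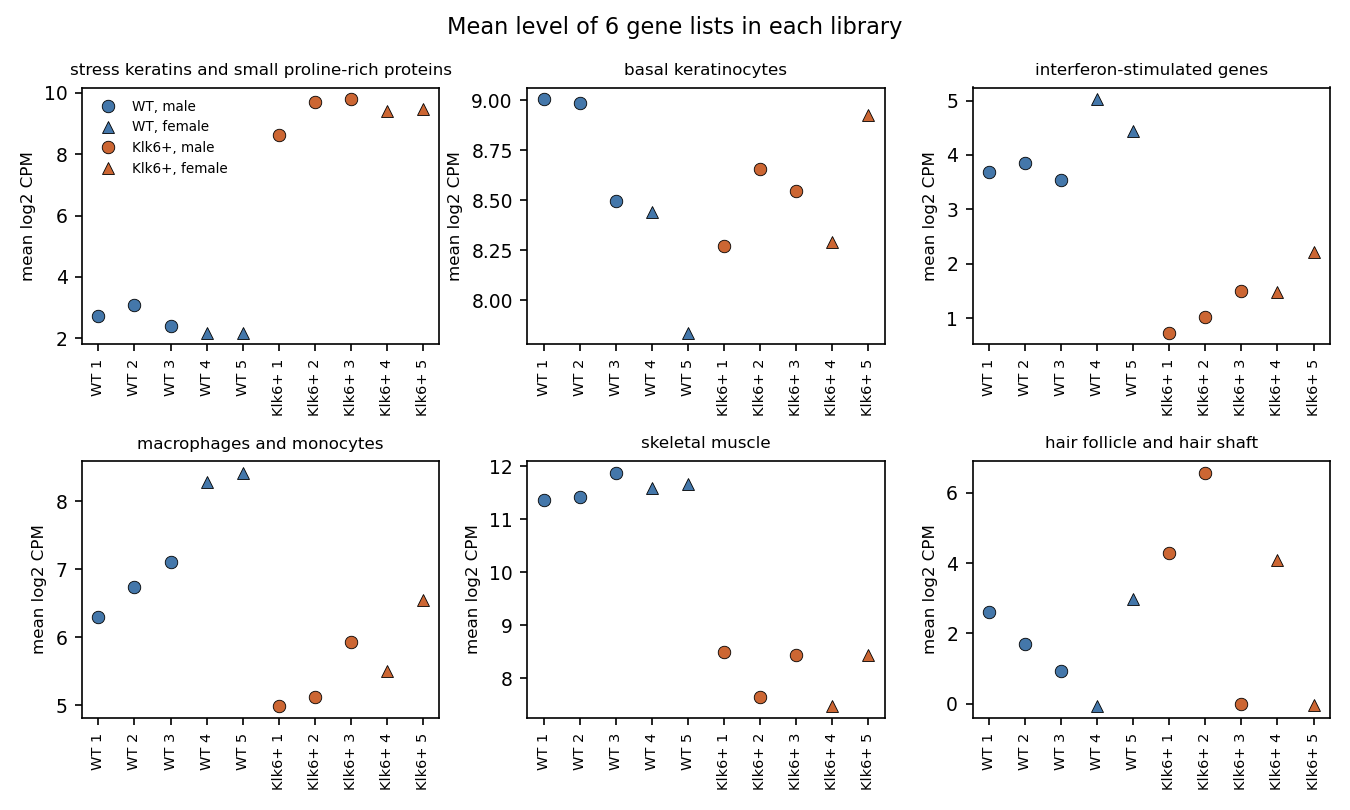
Mean log2 CPM of 6 gene lists (vertical axis) in each library (horizontal axis); circles are males, triangles females, blue WT and orange Klk6+. Interferon-stimulated genes and skeletal muscle are lower in every Klk6+ library than in any WT library, and the hair list of Klk6+ 3 (-0.02) and Klk6+ 5 (-0.05) lies far below that of the other Klk6+ libraries.

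The sex of each mouse allowed the genotype effect to be estimated in males and in females. It was called for 9573 genes in the 3 against 3 males (4962 higher and 4611 lower) and for 8863 genes in the 2 against 2 females (4644 higher and 4219 lower). Klk6 was 9.36 ± 0.28 higher in males and 9.60 ± 0.35 higher in females on the log2 scale. The smallest p-values in both sexes included the stefin genes Stfa3 (8.83 ± 0.24 in males and 8.51 ± 0.29 in females), BC117090 (8.69 ± 0.25 and 9.06 ± 0.32) and Stfa1 (8.52 ± 0.27 and 8.90 ± 0.34). Among genes that fell were Sema3b (-3.31 ± 0.11 and -2.64 ± 0.13), which encodes a secreted guidance cue, and Kctd12 (-2.98 ± 0.11 and -3.14 ± 0.13). The carbonic anhydrase gene Car12 rose by 4.94 ± 0.18 in females. In males Car12 was higher in Klk6+ too, at 8.79 to 12.6 CPM in WT and 177 to 188 CPM in Klk6+. The stress keratin list had a median of 8.54 in males and 9.22 in females, and the interferon list -2.62 and -3.10. Other list medians were less alike. They were -0.128 in males and 0.688 in females for basal keratinocytes, -0.008 and 0.728 for chemokines, and 3.99 and 1.22 for the hair list. Differences of list medians between the sexes were not tested. Across the 14861 genes, which are not independent replicates, the male and female log2 fold changes had a Pearson correlation of 0.913 and a Spearman correlation of 0.914, and 7810 of the 7822 genes called in both sexes moved in the same direction.

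No gene passed the edgeR test of the genotype-by-sex interaction, with a smallest adjusted p of 0.128. At an unadjusted p below 0.05 there were 1410 genes (9.49%). limma-voom called 0 genes and DESeq2 called 263; in simulated data DESeq2 made 45 false calls in this test, against 2 by edgeR and 2 by limma-voom. Without WT 3 the edgeR test called 4 genes, and without Klk6+ 4 it called 1. With 2 females per genotype the test recovered 55.4% of 4-fold differences and 6.06% of 2-fold differences in simulated data.

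**Figure D4:**
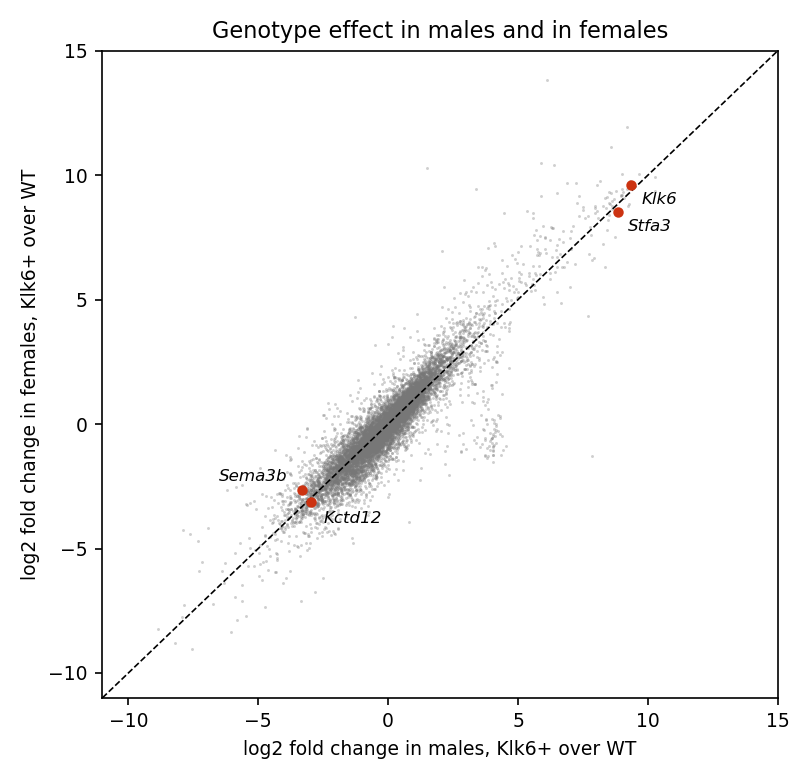
Log2 fold change of Klk6+ over WT in males (horizontal axis) and in females (vertical axis); each grey point is 1 of 14861 genes, the dashed line marks equal values, and red points name 4 genes. The points follow the line, with Klk6 at 9.36 and 9.60.

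Between the sexes, at equal genotype, 6 genes differed. The Y-linked Ddx3y (-8.80), Eif2s3y (-8.44), Kdm5d (-7.85) and Uty (-7.26) were lower in females (adjusted p = 9.73e-09, 2.2e-06, 1.23e-05 and 3.38e-07), as the sex labels require. The X-linked Kdm6a (0.71, adjusted p = 0.0184), which escapes X inactivation, and S1pr2 on chromosome 9 (0.84, adjusted p = 0.0453), which encodes a sphingosine 1-phosphate receptor, were higher in females. Kdm6a lost its call without any one of 6 single libraries (adjusted p up to 0.147, without WT 4) and S1pr2 without any one of 7 (adjusted p up to 0.261, without WT 4). The number of genes called rested on single libraries, with 704 without Klk6+ 4 and 347 without Klk6+ 3. It also rested on the tool, with 938 by DESeq2 and 132 by limma-voom.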

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

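In this part the tests on interferon-stimulated genes and on stress keratins were chosen after the results were seen, and the counts of other splits were planned. Values of single libraries far from the rest of their group were looked for in 424 groups of 5 libraries, the 2 genotypes for each of 180 genes, 31 lists and the total count; 37 stood out, given as the gap of the extreme library to its neighbour as a share of the group's range. The cutoff picks about 1 in 20 groups of independent, normally distributed values. That rate does not hold here, since CPM need not be normal and the genes are related to each other. Some genes were also chosen after their values were seen, and a group with counts in a single library always stands out.

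WT 3 held the highest WT values of muscle and blood genes, namely Dupd1 (0.78), Actc1 (0.786), Plcd4 (0.882), Pvalb (0.85), Alas2 (0.871) and Hba-a2 (0.894), and the only WT counts of Prl2c2 (1) and Il17a (1). WT 2 held the highest WT values of Mmp8 (0.9), Timp1 (0.88), Cxcr2 (0.733) and the growth factor genes Hbegf (0.846), Ereg (0.737) and Nrg1 (0.754), as well as of Arntl (0.747) and Clock (0.906) and the lowest of Hamp2 (0.763). WT 1 was highest for Il13ra2 (0.75), Cd3e (0.717), Cd3g (0.828), Ier2 (0.819) and Egr1 (0.814). WT 4 was highest for Ifit3 (0.714) and lowest for Mmp2 (0.752). Among Klk6+ libraries, Klk6+ 5 was highest for Krt77 (0.885), Flg2 (0.786), Lce1m (0.771), Epsti1 (0.86) and Cd3e (0.785), and Klk6+ 2 was highest for the hair genes Krt71 (0.803) and Tchh (0.861). Klk6+ 3 was highest for the mean of the IL-23 and IL-17 axis (0.782) and held the only Klk6+ count of Igsf1 (1). Klk6+ 1 was lowest for Sprr2f (0.811) and highest for Actc1 (0.729), and Klk6+ 4 was highest for Lcn2 (0.835) and lowest for Casp14 (0.751).

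Regrouping the same libraries tested whether the counts of calls could come from any division into groups. For genotype, 1 of 100 splits drawn from 126, the real one, gave as many as 10813 genes, and the highest of the others gave 0. For changes of 2-fold or more the real split was also the only 1 of 100, with 5388 genes against 0. In the other splits the genotype difference went into the spread within groups, which holds their counts down. The real split thus ranked first, but the 0 of the others does not measure what chance gives. For the lists tested with camera, 8 of 100 splits, the real one included, called at least the 22 lists of the real split. The other splits called a median of 18 and at most 23. Each of those splits held unequal numbers of the genotypes in its groups, so part of the genotype difference stayed in it. The count therefore cannot decide whether chance gives as many lists. With fry, which tests each list by itself, the real split also ranked first of 100, with 26 lists and at most 1 in any other split. The limit given for the gene counts holds here too. In males the 10 possible splits are too few for a share below 0.05; the real split gave 9573 genes (1 split as large) and the highest other 0. For sex, 4 of 100 splits gave at least the 6 genes of the real one, and the highest other gave 716 genes. That split set WT 4, WT 5, Klk6+ 3 and Klk6+ 5 against the rest, which points to a structure of the samples beyond genotype and sex. Klk6+ 3 and Klk6+ 5 were also the Klk6+ libraries low in hair-follicle genes. The WT libraries of that split did not share this, with a hair list mean of -0.07 log2 CPM in WT 4 and 2.99 in WT 5.

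All interferon-stimulated genes tested were lower in Klk6+. An interferon response in only 1 or 2 WT mice is argued against, since the lowest WT library lay above the highest Klk6+ library for 21 of 21 genes. The interferon list fell further than the macrophage list, by a mean of -0.963 log2 CPM per library (two-sided exact permutation p = 0.00794, n = 5 each). The interferon genes thus fell more than the macrophage list as a whole, whose median was -2.02 over 15 genes. This cannot decide on a smaller share of macrophages and monocytes, because members of the macrophage list did not change alike. Cd14 rose by 1.73, while Adgre1, Ccr2 and Csf1r, which were named for their small p, fell by amounts near the interferon median of -2.83. A smaller share of dendritic cells or of skeletal muscle also stays open. The interferon list did not fall further than the dendritic list beyond the spread (-0.577, exact permutation p = 0.175). It fell less than the muscle list (a difference of 0.768). A lower interferon tone in Klk6+ skin, set against these, may also contribute and was not tested.

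Stress keratin and small proline-rich genes rose in Klk6+. A larger share of keratinocyte RNA is argued against as the whole cause, since no basal keratinocyte gene tested rose by more than 3.52 (Krt14) and their median was 0.197, against a median of 8.82 for the list. Counts freed by the fall of the 16 genes of the muscle list would raise every other gene by 0.104, below the smallest rise in the list (1.37). Counts freed by the fall of other muscle genes or other tissues are not in that value. Reads shared among Sprr2 copies cannot have raised the 7 members outside that family, which rose by 1.37 to 8.83. For the 7 Sprr2 members, which rose by 8.81 to 9.29, it stays open which copies rose, since reads of a raised copy spread over the others would give the same values. A change of epidermal state with genotype is a hypothesis consistent with these values.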

How the results depend on the processing

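The alternatives added after the data were seen were limma-trend on FPKM and no scaling beyond library size. So were the fit without the muscle list and the 50 most abundant WT genes, and Klk6+ 3 and 5 left out together. No paired analysis was possible because the replicate numbers only name the mice within each genotype. Genes called for genotype numbered 10559 with Klk6+ 3 and 5 out and 10319 to 10744 with each library left out, those of at least 2-fold 5322 to 5559, in males 8600 to 9677 and in females 6734 to 8868. Of the 10813 genotype calls, 86.8% to 99.2% were also called in each alternative. limma-trend on FPKM called 3588 genes of at least 2-fold (1732 up, 1856 down) of 12838 tested, beside 5388 of 14861 in the main fit. It changed the values, the test and the set of genes at once, and the cause of the drop was not tested. The interaction gave 263 genes with DESeq2 beside 0 in the main fit, 1 with Klk6+ 3 and 5 both left out and 0 to 4 with 1 library left out. Sex gave 20 genes without scaling (16 up, 4 down in females, beside 2 and 4), 9 with upper-quartile scaling (5 and 4), 938 with DESeq2, 132 with limma-voom and 4 to 704 with 1 library left out; the cause was not tested. Lists called were 3 with an estimated correlation and 20 to 22 with 1 library left out. Upper-quartile scaling moved the median log2 fold change of all genes from 0.04 to -0.059, and in males from 0.039 to -0.066, with 4994 genes up and 5669 down by genotype.

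The directions that turned were of results not called. With each library left out, the log2 fold change of F2rl1 ranged from -0.045 to 0.326, of Alas2 from -0.522 to 1.98, of Hba-a2 from -1.04 to 1.67 and of Egr1 from -0.22 to 0.69, the basal list median from -0.031 to 0.319 and the chemokine median from -0.151 to 0.341. With Klk6+ 3 and 5 out, Alas2 was at -1.10, Egr1 at -0.16, the basal median at -0.038 and the chemokine median at -0.48. Hba-a2 was at 0.27 with 1 surrogate variable and 0.47 with limma-voom. The causes were not tested. With Klk6+ 3 and 5 out, Cd14, Foxp3, Kynu and Timp1 lost their calls (adjusted p = 0.0645, 0.0878, 0.0785 and 0.0825), as did Spink5 (0.304), Itga6 (0.224), Atf3 (0.11) and, between the sexes, Kdm6a and S1pr2 (0.0767 each). The lists of late differentiation (0.0666), glucocorticoid and fasting response (0.0624) and the circadian clock (0.0869) also lost theirs. The hair list (median 3.49, adjusted p = 0.00303), the melanocyte list (3.22, 0.00321), Krt71 (3.90, 0.0185) and Tchh (3.48, 0.026) gained calls. Klk6+ 3 and 5 were the Klk6+ libraries lowest in both lists, so these gains follow from the choice of libraries and do not support a rise. Among named genes outside the leave-one-out fits, 2211 of the gene and alternative pairs kept direction and call, 28 lost the call, 2 gained it and 4 turned. The depth of 26521019 to 41970272 counts limits genes below 1 CPM, since 1 count was worth 0.0230 to 0.0373 CPM.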

Other observations

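The gene groups and the clock test in this part were chosen after the values were seen, so they are hypotheses for other samples. Genes of cholesterol synthesis and its regulation rose without exception among the 23 listed, by 1.03 to 4.48 on the log2 scale with a median of 2.27. Idi1, which encodes isopentenyl diphosphate isomerase, went from 83.9 ± 48.9 to 1656 ± 548 CPM (4.48 ± 0.35; mean ± SD, n = 5 each, edgeR adjusted p = 2.06e-06). For 22 of the 23 genes the libraries of the genotypes did not overlap. Camera gave p = 1.29e-11, and p = 0.0823 with an estimated correlation. Genes of the sebaceous gland, which makes lipids, rose in the same libraries (9 of 10, median 2.55). Genes of the ligands of the epidermal growth factor receptor family moved both ways, with 6 of 8 up and 2 down. Epgn (6.52 ± 0.50), Nrg1 (4.43 ± 0.80, and 5.71 without WT 2), Areg (4.42 ± 0.27), Hbegf (3.97 ± 0.34), Tgfa (2.47 ± 0.25) and Ereg (2.05 ± 0.34) rose, while Btc (-1.83 ± 0.18) and Egf (-2.80 ± 0.29) fell (camera p = 0.0343, and p = 0.341 with an estimated correlation).

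Members of 1 gene cluster of the cornified envelope differed from each other. The 6 genes Lce3a to Lce3f rose with a median of 8.59, from below 1 CPM in WT to between 134 and 174 CPM in Klk6+ (camera p = 8.54e-13, and p = 0.0177 with an estimated correlation). The 14 Lce1 genes did not pass as a group (median 1.26; camera p = 0.155, and p = 0.69 with an estimated correlation). Over both sexes 9 rose, with Lce1g (3.13 ± 0.38) ahead, and 4 were not called. Lce1m alone fell, from 608.5 ± 230.5 to 28.6 ± 19.3 CPM (-4.42 ± 0.48, and -5.05 without Klk6+ 5; edgeR adjusted p = 1.79e-05). In males Lce1l (-1.53) and Lce1a2 (-0.81) also fell (edgeR adjusted p = 0.00479 and 0.0198), against 0.20 and 0.34 in females. The log2 fold change was higher in females than in males for every Lce1 gene, but none passed the interaction test after adjustment. The Lce genes are near copies, so values of single members are uncertain. Of 11 Skint genes, which encode butyrophilin-like proteins, 10 fell, for example Skint5 (-6.03 ± 0.36) and Skint10 (-5.04 ± 0.41). Skint1 changed by -0.67 ± 0.19 (edgeR adjusted p = 0.00975), and its values overlapped between genotypes. Skint3 differed by -0.14 ± 0.16 (edgeR adjusted p = 0.437) and was called without Klk6+ 5 (-0.35, adjusted p = 0.0374). The median of the 11 genes was -2.75 (camera p = 1.07e-05, and p = 0.0622 with an estimated correlation). All 11 guanylate-binding protein genes, of which 2 were also on the interferon list, fell with a median of -2.43 (camera p = 1.21e-05, and p = 0.157 with an estimated correlation).

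The opposite moves of the clock genes have a candidate explanation in the hour of collection, which the sources used here do not give. Arntl and Dbp peak at opposite times of day, so that a later or earlier hour in 1 genotype would raise one and lower the other, as was measured (1.18 for Arntl and -4.16 for Dbp). An effect of genotype or illness on the clock, or on cells that contribute these transcripts, would give the same values, so the explanations cannot be told apart with the hour unknown. WT 2 had the highest Arntl among WT libraries (27.0 CPM against 8.52 to 13.2) and the lowest Dbp (45.5 CPM), but even that Dbp lay far above the Klk6+ libraries (3.61 to 6.83 CPM).

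Macrophage genes also differed between WT mice. Their mean level was 6.30, 6.74 and 7.10 log2 CPM in the WT males and 8.28 and 8.42 in the WT females, so that the WT females stood above the WT males. In Klk6+ the sexes overlapped, with 4.98, 5.11 and 5.93 in the males and 5.50 and 6.55 in the females. These differences were seen after the fact and were not tested.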
